A study of Mus musculus with 338 samples.

How the data were processed

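Total RNA of mouse pancreatic islets was sequenced in 338 libraries, each from 1 mouse. Per the labels, at least 150 islets per mouse were lysed, and each library was made from 200 ng of total RNA with the TruSeq RNA v2 kit. The kit selects polyadenylated RNA and keeps no strand, so reads of an overlapping or antisense transcript cannot be told from those of the gene itself. Per the submitters' processing notes, TopHat 1.3.3, SAMtools 0.1.16, HTSeq 0.5.3p3 and edgeR (no version given) were used with the genome build mm9. Genes are named by symbol, the only identifier in the deposited tables.

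The deposited raw table holds a count of reads per gene and library, as whole numbers, for 21382 genes. It also gives the total of sequenced and of mapped reads, and the gene counts summed to the total of mapped reads in all 338 libraries, so that total is the number of reads assigned to genes. The authors' normalized table holds log2 values of 14826 genes. Each value equals log2 of the count times 1 factor per library plus 1, with factors from 0.428 to 2.94, and the table holds the genes whose mean count is 10.0 or higher. The raw counts were used throughout, and the normalized table as an alternative.

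The total assigned to genes ran from 9526926 to 50751894 reads per library (median 25989180). Levels are given as CPM, counts scaled to the library total without TMM factors, while fold changes and correlations were taken from TMM-scaled values, and a gene with no count in a library is below a floor of 3 counts. Intervals and floors of this kind cover counting error only. Within groups, pairs of libraries differed by more than counting error (chi-square per degree of freedom from 4.20 over 1069 pairs, median 37.1), so counting error alone understates the spread between libraries, in which mice and library preparation are not separated.

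Samples were grouped by strain, diet and time point as labelled, which gave 48 groups of 4 to 11 mice. Genes were kept by edgeR's filterByExpr over the 48 groups (16498 genes). Counts were scaled by TMM and fitted with edgeR 4.0.16 in R 4.3.3 by the robust quasi-likelihood method, with 1 mean per group and a prior count of 2 for fold changes. The contrasts were the diet effect (HFHS minus RC) at each time point as the mean over the 6 strains, the diet effect at day 90 in each strain, the strain by diet interaction at day 90, the day 90 diet effect minus that of day 2, each strain against the mean of the other 5 on RC, and day 90 minus day 2 on RC. Genes passed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, and for strains also at a log2 fold change of at least 1 in size. The standard error (SE) was the log2 fold change divided by the square root of the F statistic.

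Before the data were examined, 25 gene lists were fixed, the contrasts and alternatives were chosen, and a rule for naming genes was written. The lists were beta cell, alpha cell, delta and PP cell, genes low in mature beta cells, insulin granule exocytosis, acinar cell, duct cell, stellate cell and fibroblast, endothelial cell, macrophage, lymphocyte, adipocyte, red blood cell, cell cycle, endoplasmic reticulum (ER) stress and protein folding, cholesterol synthesis, fatty acid synthesis, fatty acid elongation and desaturation, fatty acid oxidation with targets of the PPAR nuclear receptors, oxidative phosphorylation, glycolysis, interferon response, antigen presentation, immediate early and isolation stress, and the circadian clock. The red blood cell list had too few genes past the filter, so 24 lists were tested by camera (limma 3.58.1) with a preset correlation of 0.01 in 11 contrasts, adjusted over all of these tests, and again with an estimated correlation. Genes named are Elovl2, the genes with the largest changes past the threshold (mean CPM at least 5; at days 2, 10, 30 and 90 and for time, the same sign in all 6 strains), the 12 smallest p of the interaction, and up to 4 members of a list with the smallest p, with Ins1, Ins2, Gcg, Sst and Ppy always allowed. Genes known only by an identifier and predicted genes were skipped, and the text leaves out some genes that the rule selects. Elovl2 was set against 15 measures fixed beforehand, over mice, after the group mean was removed, by Pearson's and Spearman's correlation with 100000 permutations (two-sided, smallest possible p 1e-05).

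Alternatives fixed beforehand were DESeq2 size factors, no filter on low counts, the DESeq2 1.42.0 Wald test, limma voom with sample quality weights, limma on the authors' table, the mean of the acinar list as a covariate, the samples of 1 comparison alone, the mouse number as a replicate block, leaving out mouse 6RC89 (whose description holds an editing mark) or the 129S2/SvPas mice numbered 75 or higher, and leaving out each mouse of the smallest groups. Further alternatives were added after the data were seen, because of the patterns in the libraries described with the data: a curve of each library on gene GC content as an offset (natural spline, 5 degrees of freedom), leaving out the libraries beyond a GC slope of 0.5 log2 per 10 points, leaving out the 9 libraries that resemble another strain, a curve offset or the slope as a covariate of every gene together with leaving out those 9, and leaving out each day 90 library in turn. GC content was found for 98.3 percent of the genes by symbol. No library and no column was left out of the fit that gave the values reported.

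The procedure was tested on simulated data with the depth and spread of the libraries and 200 changed genes. At day 90 it recovered 27 of 50 genes changed 1.25-fold, 48 of 50 changed 1.5-fold and all 50 changed 2-fold, and called 8 of the unchanged genes. Simulated libraries with the same changed genes and the GC curves of the real ones were tested the same way.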

Results

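RNA of pancreatic islets was measured in mice of 6 inbred strains (C57Bl/6J, DBA/2J, BALB/cJ, A/J, AKR/J and 129S2/SvPas) kept on a high-fat, high-sugar diet (HFHS) or on regular chow (RC) for 2, 10, 30 or 90 days. There were 172 mice on HFHS and 166 on RC, in 48 groups of 4 to 11. HFHS and RC held 40 and 36 mice at day 2, 36 and 32 at day 10, 47 and 48 at day 30, and 49 and 50 at day 90. A library had 13538783 to 78334782 sequenced reads, and 9526926 to 50751894 reads assigned to genes. The insulin genes Ins1 and Ins2 together took 0.24 to 43.6 percent of these.

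Libraries differed in how counts depended on the GC content of the gene. The slope of log2 deviation on GC content ran from -3.21 to 0.667 log2 per 10 GC points, and 39 libraries lay beyond 0.5 in size, 37 of them with low counts for GC-rich genes. They fell in 14 groups, held all 6 libraries of BALB/cJ HFHS at day 2 and 7 of 8 of DBA/2J RC at day 90, and were spread unevenly over diets (11 HFHS and 5 RC libraries at day 2, 5 and 9 at day 90). Within this bound no BALB/cJ value is left at day 2 and no DBA/2J value at day 90, so means over strains there and for time on RC are over 5 strains. The insulin share had a median of 22.5 percent in the 299 libraries within this bound and of 2.55 percent in the 37. In simulated libraries with these GC curves and 200 changed genes, 4664 of the 15793 genes left unchanged were called for DBA/2J at day 90, 954 at day 2, 36 at day 90 and 1 for AKR/J at day 90, against 8, 1, 8 and 2 once the curves were fitted as an offset. The simulated bias had the form that the offset fits, so these counts do not show how well the offset corrects the real libraries.

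**Figure D1:**
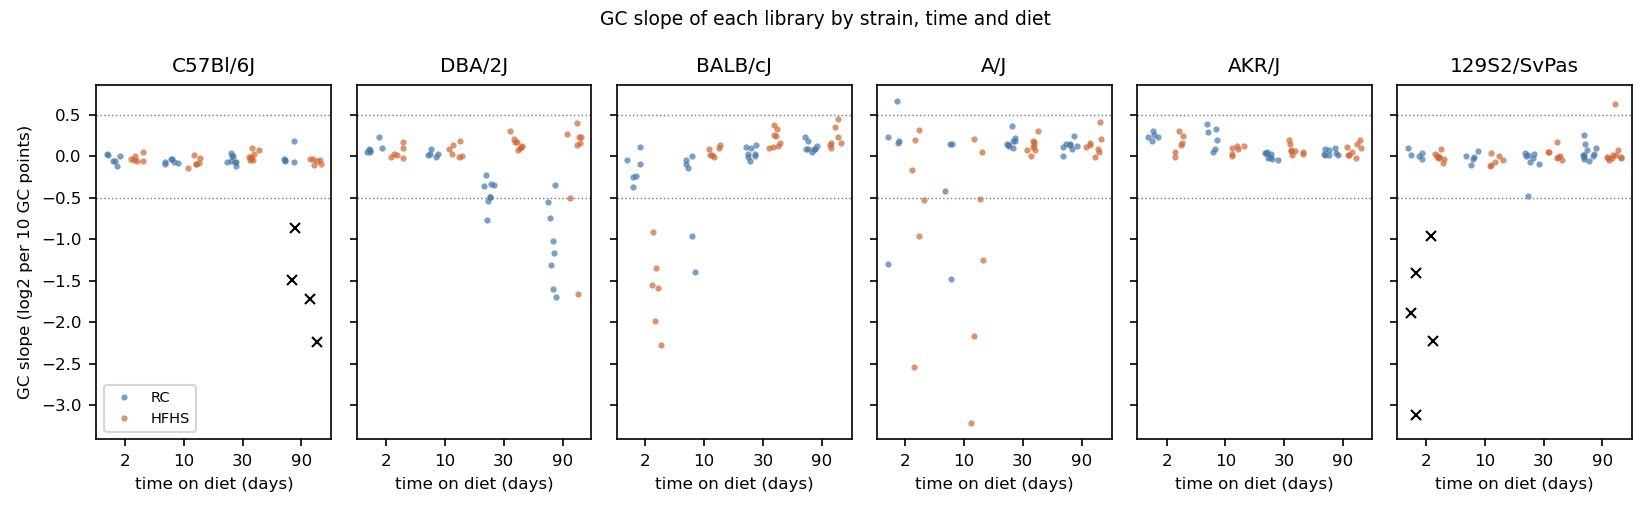
GC slope of each library (log2 per 10 GC points) by strain, day on diet and diet, 1 point per mouse, with dashed lines at the bound of 0.5 in size. All 6 BALB/cJ HFHS libraries of day 2 and 7 of 8 DBA/2J RC libraries of day 90 lie below the bound.

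In 9 libraries, 42 genes that tell the strains apart matched another strain better than the labelled one. The libraries labelled C57Bl/6J day 90 1HF155, 1HF156 and 1RC134 were closest to 129S2/SvPas, and 1RC133 to BALB/cJ. The libraries labelled 129S2/SvPas day 2 6HF5, 6HF6, 6RC2, 6RC5 and 6RC6 were closest to C57Bl/6J, though Col6a6 was at 12.7 CPM in 6RC5, 16.8 in 6RC6, 26.5 in 6RC2 and 54.1 in 6HF6, under its lowest of 55 in C57Bl/6J. All 9 were beyond the GC bound and were found again with the GC curves removed, while the other 30 libraries beyond the bound were closest to their own strain.

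**Figure D2:**
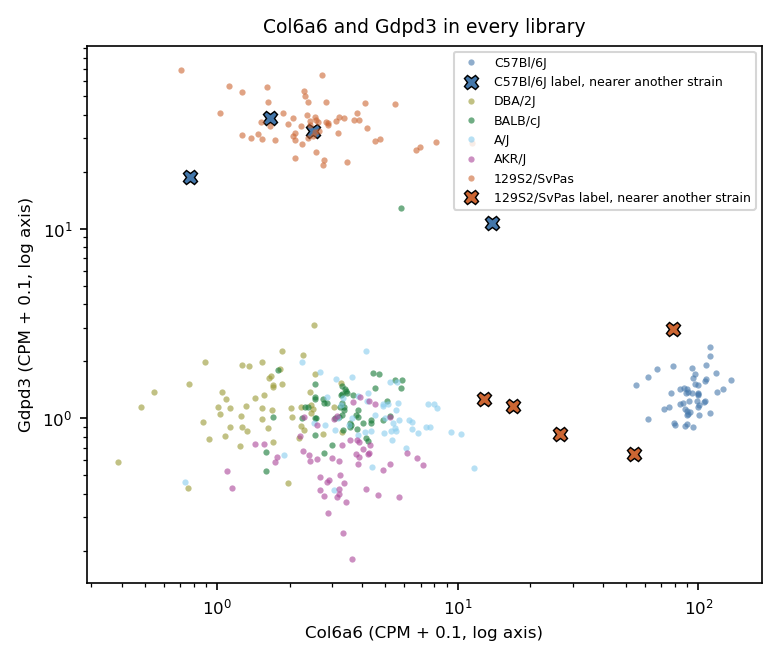
Level (CPM + 0.1, log axes) of Col6a6, high in C57Bl/6J, against Gdpd3, high in 129S2/SvPas, in each library, coloured by labelled strain. Crosses are the 9 libraries that resemble another strain.

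Elovl2, named in the title of the series, encodes an elongase of long polyunsaturated fatty acids, and its mean level was 35.5 CPM. CPM levels hold no TMM factors, which the fold changes do, so the ratio of 2 levels differs from the fold given beside them. On RC it was higher than the mean of the other strains in BALB/cJ (log2 fold change 0.74, SE 0.0469, adjusted p = 3.04e-39) and in 129S2/SvPas (0.43, SE 0.0466), and lower in AKR/J (-0.69, SE 0.0537), DBA/2J (-0.29) and A/J (-0.28). C57Bl/6J did not pass (0.08, adjusted p = 0.166). At day 90 it rose on HFHS in AKR/J by 0.50 (SE 0.118, adjusted p = 0.000918), from 27.7 ± 2.98 to 34.5 ± 6.47 CPM (SD, n = 8 each), and this call was kept without any 1 AKR/J library. In DBA/2J it fell by 0.27 (SE 0.118, adjusted p = 0.0434), from 42.7 ± 9.4 to 29.7 ± 10.8 CPM (SD, n = 8 each), but with the GC curves as an offset the fold was 0.14 (adjusted p = 0.145). That DBA/2J call was lost without any of 2HF129, 2HF130 (adjusted p = 0.137), 2HF131, 2HF132, 2HF133, 2HF134, 2RC117, 2RC120 or 2RC121. The diet effect differed between strains (interaction adjusted p = 0.000749). As the mean over strains it was 0.23 at day 2 (SE 0.0552, adjusted p = 0.000657), 0.00 at day 10, -0.12 at day 30 (adjusted p = 0.0783) and -0.02 at day 90 (adjusted p = 0.762). The day 2 value was 0.11 without the libraries beyond the GC bound (adjusted p = 0.0659), which leaves out BALB/cJ; over the same 5 strains it was 0.15 with all libraries. At day 2 the BALB/cJ mice had 93.7 ± 14.6 CPM on HFHS (SD, n = 6) and 51.1 ± 3.89 on RC (SD, n = 6). On RC it rose from day 2 to day 90 by 0.15 (adjusted p = 0.0247), and by 0.02 within the GC bound (adjusted p = 0.744).

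**Figure D3:**
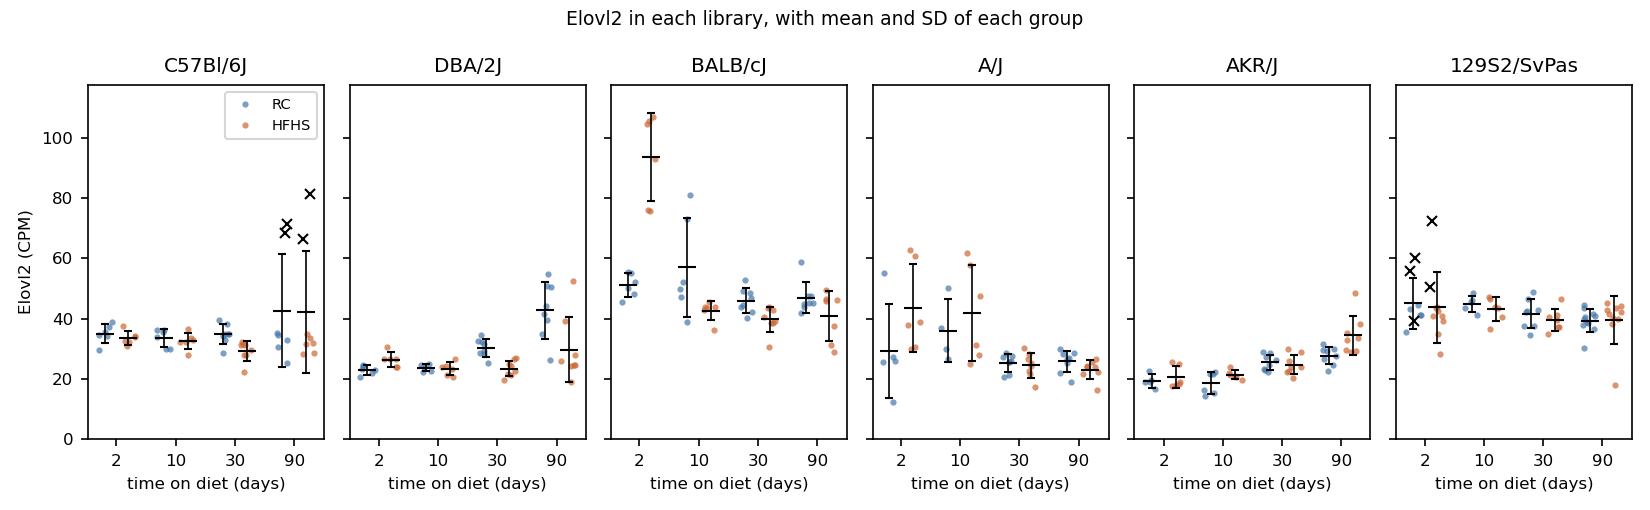
Elovl2 level (CPM, without TMM factors) of each mouse by strain, day on diet and diet, with the group mean and SD, and crosses for the 9 libraries that resemble another strain. In AKR/J at day 90 the HFHS mean of 34.5 lies above the RC mean of 27.7, and the BALB/cJ HFHS mean of 93.7 at day 2 belongs to the 6 libraries beyond the GC bound.

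Over all mice, with group means removed, Elovl2 correlated negatively with Ins2 (Pearson's r = -0.696, Spearman's rho = -0.441, permutation p = 1e-05 each, the smallest possible; adjusted p = 1.36e-05 and 1.87e-05 over 15 relations). Without the 2 mice farthest from the median r was -0.679. Within the strains r was -0.881 in C57Bl/6J, -0.668 in DBA/2J, -0.516 in BALB/cJ, -0.854 in A/J, -0.0237 in AKR/J and -0.642 in 129S2/SvPas. It was -0.197 (rho = -0.136, adjusted p = 0.0091 and 0.0596) in the 299 libraries within the bound, and 0.0271 with the GC curves removed. Within the bound r was still -0.695 in A/J (rho = -0.629, n = 43), and -0.268 in C57Bl/6J, 0.0831 in DBA/2J, -0.0908 in BALB/cJ, -0.0237 in AKR/J and -0.188 in 129S2/SvPas. With the GC curves removed it was -0.11 in A/J, -0.612 in C57Bl/6J, 0.172 in DBA/2J, 0.0127 in BALB/cJ, 0.217 in AKR/J and 0.543 in 129S2/SvPas. Elovl6, another elongase, had an r of 0.688, 0.353 and 0.195 in these 3 sets (adjusted p = 1.36e-05, 0.00015 and 0.00544), and its rho was 0.522, 0.313 and 0.124 (adjusted p = 1.87e-05, 0.00015 and 0.0864). By strain, r with Elovl6 was 0.83 in A/J, 0.504 in BALB/cJ, 0.283 in 129S2/SvPas, 0.134 in AKR/J, 0.12 in DBA/2J and 0.0912 in C57Bl/6J within the bound, and 0.636, 0.327, -0.0176, -0.0569, -0.105 and 0.313 with the GC curves removed.

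At day 2, 17 of 28 genes of fatty acid oxidation rose on HFHS and 14 of 25 genes of cholesterol synthesis fell, as the mean over the 6 strains. Cpt1a, the carnitine palmitoyltransferase that admits fatty acids to mitochondria, rose by 0.56 (SE 0.0581, adjusted p = 4.09e-15), Pdk4, a kinase that restrains glucose oxidation, by 0.77 (SE 0.119, adjusted p = 1.45e-07), and Rbp7, a retinol-binding protein gene, by 0.92 (SE 0.11, adjusted p = 3.86e-12). The clock gene Npas2 fell by 0.96 (SE 0.094, adjusted p = 7.42e-17) and Per3 rose by 0.72 (SE 0.0916, adjusted p = 5.79e-11). Arl4d, Adcy1 and Inhbb rose (0.86, 0.67 and 0.66), and Col1a1, Mfap4, Col16a1, Slc41a3 and Bbc3 fell (-1.12, -0.93, -0.92, -0.85 and -0.92). With the GC offset Col1a1 was at -0.68, Col16a1 at -0.45 and Inhbb at 1.08. Bbc3 did not pass with the GC slope as a covariate without the 9 libraries (-0.24, adjusted p = 0.0602).

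Of 28 genes of fatty acid oxidation, 17 rose and 0 fell (18 and 1 when adjusted over the list alone), Slc25a20 by 0.30 (SE 0.0514). The camera test gave adjusted p = 3.36e-05, and adjusted p = 0.508 with an estimated correlation. Of 25 genes of cholesterol synthesis, 0 rose and 14 fell (15 adjusted over the list alone), and camera gave 6.76e-06, and adjusted p = 0.127 with an estimated correlation. Of the 15 clock genes 8 rose, 4 fell and 3 did not pass, and the list had no call (camera adjusted p = 0.0728; 0.000101 with the GC offset).

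Further lists were called down at day 2. Of the cell cycle list 19 of 32 fell (Ube2c -0.93, Cdc20 -0.82; camera adjusted p = 1.3e-07), of the stellate cell list 8 of 12 (Col1a2 -0.70; 0.000349), of the macrophage list 9 of 12 (C1qa -0.72; 0.000197), of the acinar list 11 of 27 (Prss1 -2.02; 0.000202), of the antigen presentation list 9 of 14 (0.00155) and of the lymphocyte list 3 of 12 (0.0488), with 0 risen in each. These gave adjusted p = 0.665, 0.654, 0.619, 0.839, 0.734 and 0.88 with an estimated correlation. With the GC offset Col1a2 was at -0.41 and C1qa at -0.34, and within the GC bound Cdc20 was at -0.53. Of 12 endothelial genes 7 fell and of 10 duct genes 4, with 0 risen and no list call (camera adjusted p = 0.0508 and 0.0673). The antigen presentation call was lost within the GC bound (adjusted p = 0.102), the acinar call with the slope covariate (0.07) and the lymphocyte call without the 9 libraries (0.235). Of 7 adipocyte genes 3 rose (camera adjusted p = 3.05e-05; adjusted p = 0.0942 with an estimated correlation). Adipoq, an adipocyte hormone, reached 11.2 CPM in the BALB/cJ HFHS library 3HF4 and 5.62 in the A/J HFHS library 4HF4, against at most 0.035 and 0.0598 CPM in the RC libraries of these strains. Of 24 beta cell genes 3 rose and 8 fell, with no call (camera adjusted p = 0.559). Mafa fell by 1.35 (SE 0.287; -0.43 within the GC bound), Ins1 by 0.71 (SE 0.183) and Ins2 by 0.77 (SE 0.182). Insulin took 2.19 ± 2.13 percent of reads (SD, n = 6) in the BALB/cJ HFHS libraries beyond the GC bound. Within the bound, which leaves out BALB/cJ, Ins1 and Ins2 were both at -0.10 (adjusted p = 0.203 and 0.276), and over the same 5 strains with all libraries at -0.16 and -0.17.

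In all, 6757 genes passed at day 2, 3051 higher and 3706 lower. The count was 3290 with the GC offset (1752 higher and 1538 lower), 3284 within the GC bound (1793 and 1491), 3553 with the slope covariate without the 9 libraries (2334 and 1219), and 1875 in the day 2 samples alone, while the authors' table gave 1388 higher and 4284 lower, and 890 genes passed with the same sign in the fit reported and in the 4 GC or strain settings compared (GC offset, GC bound, without the 9 libraries, slope covariate).

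At day 10, 8 of the 28 fatty acid oxidation genes rose. Cpt1a rose by 0.74 (SE 0.0613, adjusted p = 2.86e-23) and Angptl4, an inhibitor of lipoprotein lipase, by 1.53 (SE 0.227, adjusted p = 3.08e-07). The neuropeptide genes Vip and Npy fell by 0.99 (SE 0.196, adjusted p = 0.000721) and 0.61 (SE 0.15, adjusted p = 0.0147). Adcy1, Inhbb, Pdk4, Gabra4 and Myc rose (0.81, 0.80, 0.61, 0.60 and 0.53), and Slc2a1, Dnajb5, Ptges and C8b fell (-0.41, -0.41, -0.41 and -0.37). Slc2a1 did not pass on the authors' table (adjusted p = 0.0708). Of the 28 oxidation genes 0 fell (10 rose adjusted over the list alone), with Slc25a20 at 0.36, and camera gave 6.14e-13 (adjusted p = 0.0902 with an estimated correlation).

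Other lists at day 10 were called on small shifts. Of 25 ER stress genes 0 rose and 2 fell, Pdia4 by 0.22 (camera adjusted p = 0.00961; adjusted p = 0.699 with an estimated correlation). No member passed in the cholesterol synthesis list, called down (camera 0.00155; 5 fell adjusted over the list alone), the stellate list, called down (0.0123), or the cell cycle, macrophage, lymphocyte and acinar lists, called up (0.00047, 0.0375, 0.0273 and 0.0134). With an estimated correlation these gave adjusted p = 0.44, 0.774, 0.83, 0.839, 0.88 and 0.897. Within the GC bound the macrophage, lymphocyte and acinar calls were lost (0.0555, 0.201 and 0.336). Ins1 and Ins2 were at -0.06 and -0.05 (adjusted p = 0.963 and 0.966). The genes past the threshold were 68 higher and 88 lower. With DESeq2 size factors 86 were higher and 64 lower. Without the A/J RC library 4RC13 the count was 95, while it was 332 with the GC offset (174 of them higher) and 1078 within the GC bound.

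At day 30 Cpt1a rose by 0.65 (SE 0.051, adjusted p = 6.94e-26), Inhbb, a subunit of activin, by 0.90 (SE 0.0974, adjusted p = 5.58e-14) and Adcy1 by 0.84 (SE 0.12, adjusted p = 2.14e-08). Vip fell by 1.47 (SE 0.169, adjusted p = 1.67e-12), Npy by 0.82 (SE 0.128, adjusted p = 4.69e-07), and Slc5a7, Fn1, Pdgfra and Fndc1 by 0.84, 0.78, 0.75 and 0.74. Scand1, Rps16 and Rnaseh2c rose (1.58, 0.99 and 0.78) through DBA/2J, where they were at 8.5, 4.75 and 3.59, and were at 1.01, 0.63 and 0.38 with the slope covariate. Rps16 shares sequence with its pseudogenes.

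Of 28 fatty acid oxidation genes at day 30, 12 rose and 0 fell (15 adjusted over the list alone), with Angptl4 at 1.08 (SE 0.187, adjusted p = 8.1e-06) and Slc25a20 at 0.34 (SE 0.0453); camera gave 2.16e-12 (adjusted p = 0.0942 with an estimated correlation). Of 12 stellate genes 7 fell (8 adjusted over the list alone), Dcn by 0.69 and Lum by 0.68, with camera 1.86e-07 (adjusted p = 0.44 with an estimated correlation). Of 16 elongation and desaturation genes 0 rose and 3 fell (5 adjusted over the list alone): Scd1 (-0.53, SE 0.0999), Scd2 (-0.16) and Fads1 (-0.11), with camera 0.0253 (adjusted p = 0.44 with an estimated correlation; 0.112 with the GC offset). Of 20 interferon genes 2 rose, Irf7 by 0.67 and Bst2 by 0.40 (camera 0.0161; adjusted p = 0.83 with an estimated correlation; 0.148 within the GC bound). Bst2 did not pass with the slope covariate (0.21, adjusted p = 0.118), nor did Scd2 (-0.10, adjusted p = 0.0515). Oxidative phosphorylation was called up with 1 of 25 genes risen (camera 0.00582) and the acinar list down with 1 of 27 fallen (0.000334), and with an estimated correlation these gave adjusted p = 0.761 and 0.839. The former was lost with the slope covariate (0.174). Ins1 and Ins2 did not pass (0.14 and 0.20, adjusted p = 0.57 and 0.402), and turned to -0.20 and -0.15 with the slope covariate (adjusted p = 0.00582 and 0.0195). In all 1638 genes passed, 726 higher and 912 lower. The count was 7633 in the day 30 samples alone and 6767 within the GC bound (3548 higher and 3219 lower), where the fold change still followed GC content (r = 0.607).

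At day 90, 10 of 28 fatty acid oxidation genes and 22 of 32 cell cycle genes rose on HFHS, and Npy fell. Cpt1a rose by 0.48 (SE 0.0502, adjusted p = 9.29e-15), Gucy2c, a guanylate cyclase receptor, by 0.71 (SE 0.0768, adjusted p = 2.96e-14), Dapl1 by 0.70 (SE 0.0867, adjusted p = 4.78e-11), Smoc1 by 0.58 (SE 0.0709, adjusted p = 4.49e-11) and Adcy1, an adenylate cyclase, by 0.79 (SE 0.119, adjusted p = 1.01e-07). Npy fell by 0.92 (SE 0.129, adjusted p = 7.8e-09), the acetylcholine receptor subunit Chrna4 by 0.80 (SE 0.113, adjusted p = 1.03e-08) and C8b by 0.64 (SE 0.08, adjusted p = 8.17e-11). Necab2, Gpx2 and Me3 rose (0.63, 0.62 and 0.57; Necab2 0.29 with the GC offset), and Edil3, Itgad, Adam32, Gstm2, Kcna2, Fmo1 and Synpr fell (-0.63, -0.60, -0.47, -0.43, -0.43, -0.42 and -0.41; Fmo1 -0.24 within the GC bound). Klc3, Dohh, Esrra, Cenpf and Endog also rose (0.85, 0.63, 0.62, 0.59 and 0.57). Within the GC bound, which holds no DBA/2J value, these were at 0.16, 0.05, 0.08, 0.26 and 0.08 and did not pass (adjusted p = 0.0637, 0.683, 0.44, 0.142 and 0.49).

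Of 28 fatty acid oxidation genes at day 90, 10 rose and 0 fell (10 adjusted over the list alone), with Angptl4 at 0.97, Acot1 at 0.58 and Slc25a20 at 0.27; camera gave 1.21e-06 (adjusted p = 0.44 with an estimated correlation). Of 32 cell cycle genes 22 rose (30 adjusted over the list alone), Plk1 by 0.69 (SE 0.126) and Cdc20 by 0.60 (SE 0.14), and camera gave 6.18e-09 (adjusted p = 0.619 with an estimated correlation). Within the GC bound Plk1 and Cdc20 were both at 0.25 (adjusted p = 0.137 and 0.188). Of 25 ER stress genes 5 rose, Derl3 by 0.53 (0.24 within the GC bound; camera 0.00281), and of 25 oxidative phosphorylation genes 2 rose (0.00848), and with an estimated correlation these gave adjusted p = 0.649 and 0.8. The latter was lost with the slope covariate (0.0664). The other lists had no call at day 90. Rises and falls were 3 and 5 of 24 beta cell genes, 1 and 2 of 12 alpha cell genes, 1 and 0 of 6 delta and PP cell genes, 2 and 1 of 24 exocytosis genes, 5 and 1 of 18 genes low in mature beta cells, 1 and 4 of 15 fatty acid synthesis genes, 1 and 5 of 16 elongation and desaturation genes, 0 and 1 of 16 glycolysis genes, 1 and 0 of 10 duct and of 12 endothelial genes, 3 and 3 of 19 immediate early genes and 1 and 3 of 15 clock genes. Slc2a2, the glucose transporter of beta cells, fell by 0.27 (SE 0.0544, adjusted p = 0.00017), and Aldh1a3, a gene low in mature beta cells, rose by 0.94 (SE 0.146, adjusted p = 2.19e-07; 0.37 and adjusted p = 0.0809 within the GC bound). Gcg fell by 0.25 (SE 0.0711, adjusted p = 0.00941; -0.16 and 0.111 within the GC bound). Ins1, Ins2, Sst and Ppy did not pass (0.32, 0.38, 0.19 and 0.42; adjusted p = 0.133, 0.0733, 0.107 and 0.0952). In all 2733 genes passed, 1613 higher and 1120 lower. The count was 1665 within the GC bound (775 higher and 890 lower) and 5001 without the 9 libraries. More genes were lower than higher also on the authors' table (682 higher and 1392 lower) and with the slope covariate (1047 and 1496).

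In AKR/J at day 90 (8 mice per diet) 16 of 25 ER stress genes, 21 of 32 cell cycle genes and Aldh1a3 rose, and glucagon and somatostatin fell. Aldh1a3, an aldehyde dehydrogenase low in mature beta cells, rose by 2.95 (SE 0.368, adjusted p = 2.32e-11), to 44.3 to 232 CPM in the 8 HFHS libraries from 15.2 to 31.6 in the 8 RC libraries. Gc, the vitamin D binding protein of alpha cells, rose by 1.72 (SE 0.139, adjusted p = 1.13e-24) while Gcg fell by 1.04 (SE 0.177, adjusted p = 1.57e-06) and Sst by 0.72 (SE 0.211, adjusted p = 0.00995). Dapl1 rose by 1.96 (SE 0.22, adjusted p = 8.97e-14), and Serpina7 and the gut hormone gene Cck, both chosen after their values were seen, by 1.74 and 4.26. Of 25 ER stress genes 16 rose and 0 fell (18 adjusted over the list alone), Creld2 by 1.22 (SE 0.206) and Dnajb11 by 0.77 (SE 0.117), and camera gave 1.03e-13 (adjusted p = 0.0278 with an estimated correlation). Of 32 cell cycle genes 21 rose (30 adjusted over the list alone), with Ube2c at 1.46, Cdk1 at 1.27 and Aurka at 0.89, and camera gave 9.78e-15 (adjusted p = 0.44 with an estimated correlation). Of 24 exocytosis genes 6 rose and 1 fell (7 and 1 adjusted over the list alone), Chgb by 0.88 and Scg2 by 0.71 (camera 0.016). Of 6 delta and PP cell genes 4 fell, Hhex by 0.72 (0.000222), and of 12 alpha cell genes 1 rose and 5 fell (0.0229).

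The acinar list in AKR/J was called down, with 2 risen and 4 fallen of 27 (18 fallen adjusted over the list alone; camera 5.31e-06), the clock list down with 3 of 15 fallen (0.0404) and oxidative phosphorylation up with 3 of 25 risen (0.00143). The exocytosis, delta and PP, alpha, acinar, clock and oxidative phosphorylation lists gave adjusted p = 0.508, 0.0902, 0.619, 0.722, 0.43 and 0.699 with an estimated correlation. The alpha cell call was lost with the GC offset (0.125). Beta and low in mature beta cell lists had 1 risen and 4 fallen of 24, and 4 and 3 of 18 (camera 0.597 and 0.962). Ins1 and Ins2 did not pass (0.50 and 0.43, adjusted p = 0.499 and 0.582), but passed within the GC bound (0.49 and 0.41, adjusted p = 5.51e-05 and 0.00121). The falls of the intestinal genes Akp3, Apoa4 and Alpi (-10.33, -9.95 and -9.61) were at -6.96, -7.16 and -6.60 without the RC library 5RC42, which had 64.9 CPM of Apoa4, and the calls were lost (adjusted p = 0.286, 0.307 and 0.177), that of Apoa4 also without 5HF42, 5HF43 or 5HF48. The rise of Reg3b (2.83) was lost without 5HF41 (1.01, adjusted p = 0.553), 5RC41, 5RC43, 5RC44, 5RC45, 5RC46 or 5RC47. In all 2054 genes passed, 1085 higher and 969 lower, but 853 and 1169 on the authors' table. The count was 1462 to 2410 without any 1 library, and 1939 genes passed with the same sign in the 4 GC or strain settings, none of which leaves out an AKR/J library.

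In DBA/2J at day 90 (8 mice per diet) Aldh1a3, chosen here after its AKR/J value was seen, rose by 2.72 (SE 0.37, adjusted p = 2.72e-10; 2.70 with the GC slope as a covariate), cell cycle genes rose and the neuropeptide gene Vip fell by 2.13 (SE 0.425, adjusted p = 9.67e-06). Of 32 cell cycle genes 17 rose and 0 fell, Plk1 by 2.32 (SE 0.324) and Mcm2 by 1.07 (SE 0.177; 0.47 with the GC offset), and camera gave 0.000363 (adjusted p = 0.83 with an estimated correlation). Of 19 immediate early genes 10 rose, Junb by 4.55 (1.77 with the slope covariate; camera 0.00203), and of 16 glycolysis genes 7 rose and 1 fell (0.0498), and with an estimated correlation these gave adjusted p = 0.619 and 0.839. The glycolysis call was lost with the GC offset (0.381) and turned to a fall with the slope covariate (0.00771). Of 20 interferon genes 14 fell without a list call (0.373). Oas2, an interferon-induced synthetase, fell by 2.01 (SE 0.276, adjusted p = 4.22e-10) but was at 0.02 (adjusted p = 0.952) without the RC library 2RC119, and Ddx58 fell by 0.74 but did not pass without it (adjusted p = 0.136). The largest rises were of the GC-rich genes Nrtn, Scand1 and Pcsk1n (8.11, 7.88 and 7.46; 4.6, 4.13 and 3.67 with the slope covariate). Igj fell by 2.29, was lost without 2HF133, 2HF134 or 2RC124 (adjusted p = 0.0666) and did not pass with the GC offset (-1.74, adjusted p = 0.132). Gcg fell by 0.82 (SE 0.177; -0.44 with the GC offset). Ins1 and Ins2 rose by 1.86 and 2.11 but did not pass with the slope covariate (0.09 and 0.28, adjusted p = 0.722 and 0.0779). In all 9144 genes passed, 4311 higher and 4833 lower, with 7 of 8 RC libraries beyond the GC bound. The authors' table gave 4832 higher and 3280 lower, and these samples alone 3326 and 2811. The count was 5292 with the GC offset and 3443 with the slope covariate, and 1130 genes passed with the same sign in the fit reported, with the GC offset, without the 9 libraries and with the slope covariate.

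In BALB/cJ at day 90 (7 HFHS and 8 RC mice) Rbp4, a retinol-binding protein gene of delta cells, rose by 0.76 (SE 0.151, adjusted p = 0.000739), Acot1, a PPAR target, by 1.44 (SE 0.291, adjusted p = 0.000891) and Neurog3 by 0.84 (SE 0.202, adjusted p = 0.00801). Of 28 fatty acid oxidation genes 3 rose (6 adjusted over the list alone; camera 5.25e-05), of 6 delta and PP cell genes 2 (4; 0.00047), of 18 genes low in mature beta cells 3 (4; 0.016; lost with the GC offset, 0.0542) and of 14 antigen presentation genes 2 (12; 3.57e-05). The interferon and cell cycle lists were called up with 0 genes past (5.25e-05 and 0.0182). Of 19 immediate early genes 4 fell (6; 0.0164; lost within the GC bound, 0.117) and of 25 cholesterol synthesis genes 1 (0.0498). These 8 lists, tested with an estimated correlation, gave adjusted p = 0.528, 0.0968, 0.699, 0.654, 0.631, 0.881, 0.699 and 0.699. The lymphocyte genes Hmha1, Cd52 and Arhgdib rose by 2.16, 1.99 and 1.74, and H2-Aa by 1.24. Cd52 was at 62.7 and 76.4 CPM in the HFHS libraries 3HF46 and 3HF47, and the 4 calls were lost without 3HF46 (adjusted p = 0.588, 0.622, 0.688 and 0.536), and also without 3HF47, 3RC41, 3RC42, 3RC43, 3RC44, 3RC45, 3RC47 or 3RC48. With quality weights the first 3 turned to -0.46, -0.40 and -0.27. Angptl4 rose by 2.02 and was lost without 3HF46 (adjusted p = 0.153). The heat shock genes Hspa1a, Hspa1b and Dnajb1 fell by 3.17, 2.97 and 1.54, and were lost without 3RC47 (adjusted p = 0.0823, 0.104 and 0.0636). In all 447 genes passed, of which 294 were higher, but 78 were higher and 221 lower on the authors' table, 166 and 249 in these samples alone, 810 and 895 by voom, and 789 and 1009 with the slope covariate. The count was 85 without 3HF46, 65 higher and 96 lower without 3HF47, 177 without 3RC47, 201 without 3RC48, 206 without 3RC45, 237 without 3RC44, 244 without 3RC43, 253 without 3RC42 and 845 without 3RC46.

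In 129S2/SvPas at day 90 (10 HFHS and 11 RC mice) the regenerating gene Reg3b fell by 4.99 (SE 0.965, adjusted p = 0.00077), Reg2 by 3.79 (SE 0.798, adjusted p = 0.00276), and Acot1 rose by 1.17 (SE 0.249, adjusted p = 0.00301); all 3 were kept without any 1 library. In the day 90 samples of this strain alone, Reg3b and Reg2 did not pass (adjusted p = 0.138 and 0.0917). Of 28 fatty acid oxidation genes 4 rose (5 adjusted over the list alone; camera 5.67e-06). Of 12 macrophage genes 3 fell (9; 1.43e-06). The delta and PP cell list was called up with 0 of 6 genes past (2; 5.82e-06), and it held with an estimated correlation (adjusted p = 0.0202). Endothelial (0.000958) and alpha cell (0.00472) lists were called up, and antigen presentation (0.000214), beta cell (0.0355) and cell cycle (0.0136) lists down, with 0 genes past. With an estimated correlation the oxidation, macrophage, endothelial, alpha, antigen presentation, beta and cell cycle lists gave adjusted p = 0.44, 0.44, 0.44, 0.445, 0.699, 0.475 and 0.88. Within the GC bound the beta cell and cell cycle calls were lost (0.0691 and 0.271). Plbd1 and Lyz2 fell by 1.69 and 1.66 and were lost without the RC library 6RC42 (adjusted p = 0.898 and 0.485), and Lyz2 also without 6HF42. The intestinal genes Sis and Fabp1 rose by 7.96 and 7.23, and were at 5.13 and 4.38 without the HFHS library 6HF41, which had 120 CPM of Sis, with the calls lost (adjusted p = 0.333 and 0.497), that of Fabp1 also without 6RC42. The genes past the threshold were 41 higher and 85 lower, but 18 and 1 on the authors' table and 556 and 485 by voom. The count was 41 without 6RC42, 70 without 6RC89 and 14 in the samples of this strain at day 90 alone (12 higher and 2 lower).

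In C57Bl/6J at day 90 (8 HFHS and 7 RC mice) Reg3b rose by 4.62 (SE 1.1, adjusted p = 0.0204), Rasd2 by 0.99 (SE 0.241, adjusted p = 0.0265) and Man1a by 0.49 (SE 0.114, adjusted p = 0.016). Reg3b was lost without 1HF160 (adjusted p = 0.125), 1HF162, 1RC131, 1RC133, 1RC135, 1RC136, 1RC137 or 1RC138, Rasd2 without 1HF157 to 1HF162, 1RC133, 1RC136 or 1RC138 (adjusted p = 0.26), and Man1a without 1HF155 (adjusted p = 0.106), 1RC133, 1RC136 or 1RC137, and without the 9 libraries (0.48, adjusted p = 0.138). Without the 9, Man1a did pass with the GC offset (0.44, adjusted p = 0.00751) and with the slope covariate (0.46, adjusted p = 0.0112). H2-Ea-ps, Dnahc17, Fam107a and Cfd fell by 6.51, 3.47, 3.20 and 6.16 and were lost without the library labelled 1RC133 (adjusted p = 0.701, 0.969, 0.696 and 0.365), where Dnahc17 had 51.6 CPM. Of 7 adipocyte genes 3 fell, Adipoq by 3.14 (camera 0.0167). Adipoq was lost without 1RC133 (0.09, adjusted p = 0.977), 1HF155, 1HF157, 1HF158, 1HF159, 1HF160 or 1HF161, and the list call was lost without the 9 libraries (0.543). Stellate (0.000981), lymphocyte (2.33e-05), ER stress (0.0171) and immediate early (5.25e-05) lists were called down and fatty acid oxidation (0.0362) up, with 0 genes past. Glycolysis (0.00864) and antigen presentation (0.016) were called down and lost without the 9 libraries (0.567 and 0.399). The cell cycle list was called down (0.00644) while its median and mean fold were 0.15 and 0.25. With an estimated correlation the adipocyte, stellate, lymphocyte, ER stress, immediate early, oxidation, glycolysis, antigen and cell cycle lists gave adjusted p = 0.528, 0.699, 0.649, 0.699, 0.44, 0.83, 0.712, 0.839 and 0.88. In all 36 genes passed, 7 higher and 29 lower. The count was 5 without 1RC133, 23 without 1HF160, 184 without 1RC134, 19 without the 9 libraries (14 higher and 5 lower; 27 and 10 with the slope covariate, 18 and 8 with the GC offset), and 0 by edgeR in the samples of this strain at day 90 alone, where 370 genes had an unadjusted p under 0.05 (DESeq2 called 31 genes and voom 183 with all samples).

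In A/J at day 90 (8 mice per diet) 3 genes passed, 2 higher and 1 lower. Gpm6a, a neuronal membrane glycoprotein gene, rose by 1.35 (SE 0.249, adjusted p = 0.00202). The neuropeptide gene Cartpt fell by 2.03 (SE 0.419, adjusted p = 0.0181) and Upk3b, a mesothelial gene, rose by 3.53 (SE 0.778, adjusted p = 0.0472), both chosen after their values were seen. The fatty acid oxidation (camera 3.46e-06; 4 risen adjusted over the list alone), immediate early (8.83e-06), lymphocyte (1.72e-05), cell cycle (0.000391), acinar (0.000805), duct (0.00503) and adipocyte (0.0311) lists were called up, and interferon (0.000685) and macrophage (0.00661) down, with 0 genes past. With an estimated correlation these gave adjusted p = 0.44, 0.429, 0.649, 0.83, 0.867, 0.54, 0.616, 0.699 and 0.712. The adipocyte call was lost with the GC offset (0.0755). Cartpt was lost without 4HF42, 4HF44, 4HF47 or 4RC45 (adjusted p = 0.108), and Upk3b without 4HF42 (adjusted p = 0.259), 4HF44, 4RC41, 4RC42, 4RC43, 4RC44, 4RC45, 4RC47 or 4RC48. Without 4HF42 Gpm6a did not pass either (adjusted p = 0.259), and the edgeR count was 0 (568 genes at an unadjusted p under 0.05, against 658 with all mice, where DESeq2 called 18 genes and voom 36). It was 1 without 4RC45, 5 without 4HF45 or 4HF48, 6 without 4HF41 or 4HF43, 10 without 4RC46 and 13 without 4HF46.

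**Figure D4:**
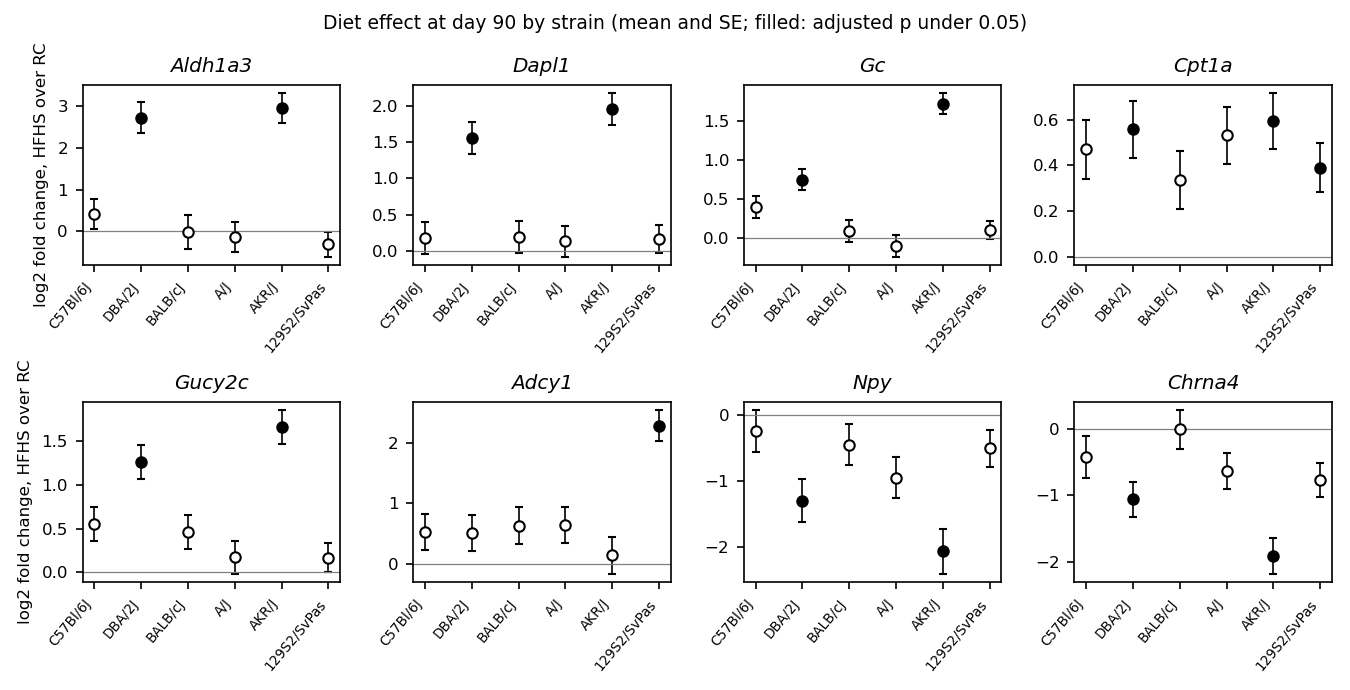
Diet effect at day 90 (log2 fold change HFHS over RC, mean and SE) by strain for 8 genes, filled where adjusted p is under 0.05. Aldh1a3 is at 2.95 in AKR/J and 2.72 in DBA/2J and does not pass in the other strains, and Gc is at 1.72 in AKR/J.

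The diet effect at day 90 differed between strains for 8304 genes. Usp11, a deubiquitinase, had the smallest p (interaction adjusted p = 6.69e-19), with -0.81 in AKR/J, -0.63 in DBA/2J and 0.01 to 0.06 in the other 4 strains. Aldh1a3 (2.94e-12) was at 2.95 in AKR/J and 2.72 in DBA/2J, and Gc (6.37e-17) at 1.72 in AKR/J, 0.74 in DBA/2J and 0.39 in C57Bl/6J. Chgb (3.8e-12) was at 0.88 in AKR/J and 0.35 in DBA/2J, Slc39a11 (2.94e-12) at 1.02 and 0.91, Hsd3b7 (3.8e-12) at 0.98 and 1.04, Rasl10b (2.62e-11) at 1.83 and 1.89, Maged2 (1.01e-10) at 0.72 and 1.04, Itpr1 (1.01e-10) at -1.09 and -0.92, and Crlf2 (5.47e-11) at 0.61 and 4.26. Nrtn and Scand1 (2.1e-13 and 7.16e-13) changed in DBA/2J and were lost within the GC bound, which holds no DBA/2J value (adjusted p = 0.624 and 0.331). Of the 8304 genes, 3545 passed in the 4 GC or strain settings. Against day 2, the day 90 diet effect differed for 8009 genes, 569 of which passed with the same sign in these settings. The rises of Mafa, H1fx, Pcsk1n, Il3ra, Dpm3 and Cd37 (2.33, 2.23, 2.08, 1.99, 1.92 and 1.87) did not pass within the GC bound (0.23, 0.04, 0.00, 0.22, 0.09 and 1.42). The falls of the intestinal genes Apoa4, Fabp2, Rbp2, Apoa1, Apob and Muc13 (-5.84, -5.61, -4.07, -3.49, -3.49 and -3.46) did not either, at -5.30, -3.93, -2.50, -2.47, -1.23 and -1.47. Apoa4 was at 1970 CPM in the HFHS day 2 library 4HF3, 1380 in 6HF1 and 1070 in 2HF111. The count was 4134 with the GC offset, 1854 within the bound and 2386 with the slope covariate.

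On RC each strain was set apart from the mean of the other 5 by 676 to 1080 genes with a log2 fold change of at least 1 in size: 720 in C57Bl/6J, 1080 in DBA/2J, 681 in BALB/cJ, 772 in A/J, 885 in AKR/J and 676 in 129S2/SvPas. The collagen gene Col6a6 was highest in C57Bl/6J (4.59, SE 0.128), the scavenger receptor gene Stab2 in DBA/2J (5.46, SE 0.142), the dynein gene Dnahc17 in BALB/cJ (6.83, SE 0.131), Tubb1 in A/J (2.70, SE 0.115), Rab3c in AKR/J (2.99, SE 0.0737) and the phosphodiesterase gene Gdpd3 in 129S2/SvPas (4.84, SE 0.134). Further genes were Rnf150 (3.05), Tdrd6 (-5.07) and Clca3 (-5.18) in C57Bl/6J, Ddit4l (3.98), Folr1 (-5.26), Gcnt1 (-4.63) and Fggy (-3.61) in DBA/2J, Itih1 (3.23), Adamts18 (-6.21) and Nptxr (-3.90) in BALB/cJ, Ctrc (-4.57) and Reg2 (-4.42) in A/J, Akp3 (3.50) and Akr1e1 (-3.35) in AKR/J, and Reg2 (4.17), Cttnbp2 (-2.90) and Itih1 (-2.63) in 129S2/SvPas. Clca3 did not pass within the GC bound. The AKR/J value of Akp3, an intestinal gene, includes the RC library 5RC42, without which its day 90 diet call was lost, and was not tested without that library. Rps18, Rps2, Rps3a, H2-Ea-ps, H2-Q10 and Gpr137b-ps also passed. Reads shared with paralogs or pseudogenes may play a part in these, which was not tested. Without the 9 libraries H2-Ea-ps had a median of 0 CPM in C57Bl/6J and 0.0295 in 129S2/SvPas, and of 29.4 to 38.2 in the other strains. Between 570 and 639 genes per strain passed with the same sign in the 4 GC or strain settings.

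From day 2 to day 90 on RC (36 and 50 mice), all 32 cell cycle genes fell, with Ccnb2 at -1.33 (SE 0.137, adjusted p = 6.01e-17), Mki67 at -1.31 (SE 0.152) and Mcm6 at -0.92 (SE 0.0822, adjusted p = 1.64e-21), and camera gave 4.68e-52 (adjusted p = 0.0178 with an estimated correlation). Eln, elastin, fell by 1.91 (SE 0.165, adjusted p = 9.59e-23), Col3a1 by 1.33 and Sparc by 0.86, and of 12 stellate genes 10 fell (12 adjusted over the list alone; camera 8.7e-13; adjusted p = 0.11 with an estimated correlation). Nmnat2, an NAD synthesis enzyme, rose 2.46-fold (SE 0.0755 on the log2 scale, adjusted p = 1.5e-42), Rasd2 by 1.66 (SE 0.108, adjusted p = 1.06e-35) and Aldh1a3 by 1.27 (SE 0.169, adjusted p = 4.53e-11). Kcnf1 and Hspa1b rose by 1.45 and 2.53, Pbk and Cenpf fell by 1.50 and 1.41, and Tex15 rose by 1.24 but by 0.65 without the 9 libraries. Of 12 alpha cell genes 8 fell, Gcg by 0.38 (SE 0.0771), with camera 0.000161 (adjusted p = 0.224 with an estimated correlation). Of 25 ER stress genes 5 rose, Chac1 by 0.92 and Herpud1 by 0.36 (camera 0.000391; adjusted p = 0.529 with an estimated correlation; 0.22 within the GC bound). Ins1 and Ins2 did not pass (-0.19 and -0.26, adjusted p = 0.474 and 0.283). In all 3831 genes passed, 1523 higher and 2308 lower. The count was 5855 within the GC bound (3183 higher and 2672 lower), 6165 without the 9 libraries (3192 and 2973) and 6340 with the slope covariate (3690 and 2650).

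**Figure D5:**
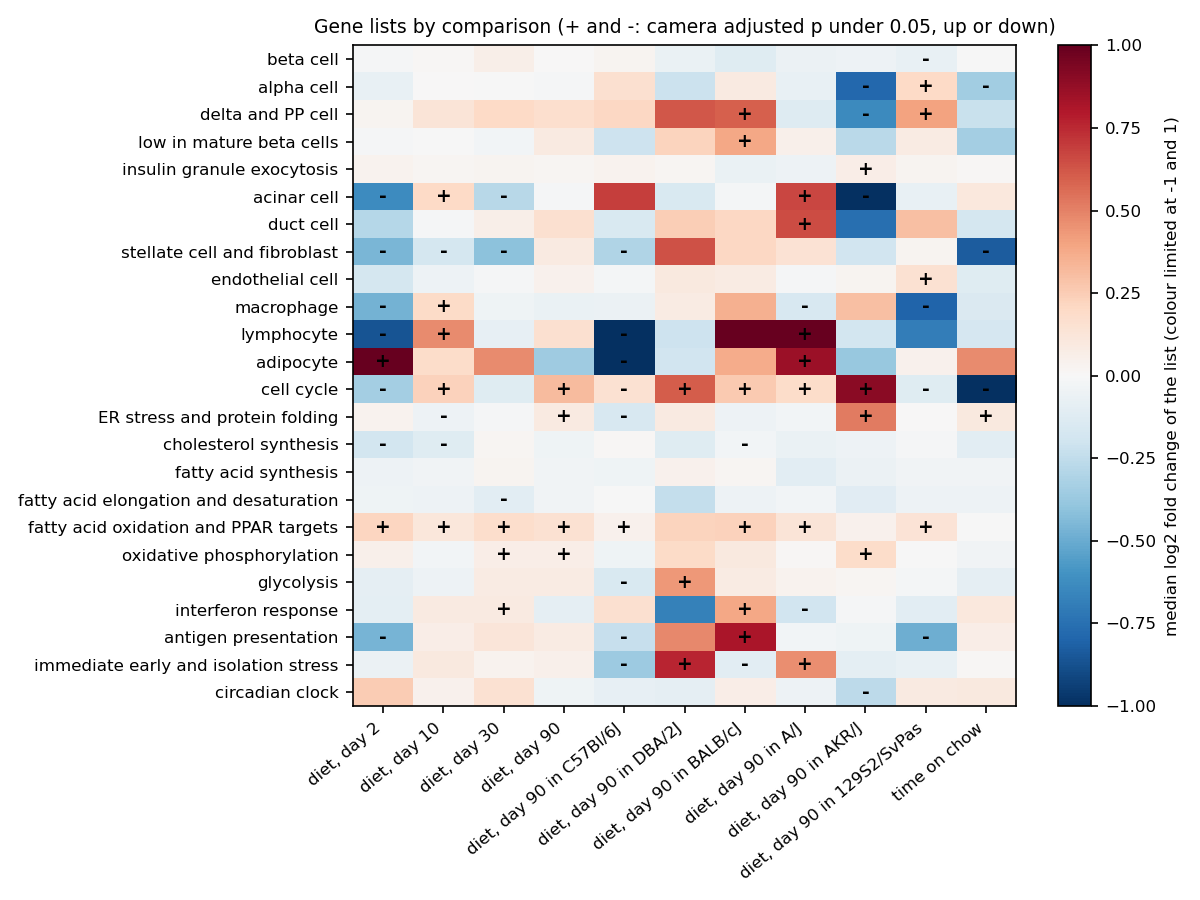
Median log2 fold change of 24 gene lists (rows) in 11 comparisons (columns), with + or - where camera with a preset correlation gave an adjusted p under 0.05. Fatty acid oxidation is called up at each of the 4 time points, and cell cycle is called down for time on RC and up at day 90. With an estimated correlation fatty acid oxidation gave adjusted p = 0.508, 0.0902, 0.0942 and 0.44 at days 2, 10, 30 and 90, and cell cycle 0.0178 for time and 0.619 at day 90.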

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

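Of the tests in this part, those on GC content, on strain levels, on mixed RNA and on insulin were chosen after the result was seen, as were the splits of the samples and their comparison by GC slope. Those on the GC slope within 8 libraries, on the slope as a covariate, on the response shared with AKR/J and on the time score were written down before their result.

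Elovl2 was checked for a mouse set apart from its group in 47 groups, and 7 mice stood out, where chance flags about 1 in 20 groups. These were 6HF6 (129S2/SvPas HFHS day 2, 72.4 CPM), 6HF99 (129S2/SvPas HFHS day 90, 17.9), 5HF48 (AKR/J HFHS day 90, 48.4), 3HF16 (BALB/cJ HFHS day 10, 36.3), 3HF26 (BALB/cJ HFHS day 30, 30.7), 3RC44 (BALB/cJ RC day 90, 58.8) and 1HF147 (C57Bl/6J HFHS day 30, 22.3). The highest, 6HF6, is 1 of the 9 libraries that resemble another strain and had a GC slope of -2.22, and 6HF99 is 1 of the 2 libraries above the GC bound.

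Effects that differed between groups by a test of the difference were the strain by diet interaction at day 90 (8304 genes, and Elovl2 with adjusted p = 0.000749) and the day 90 diet effect against that of day 2 (8009 genes, and Elovl2 at -0.26). The Elovl2 difference between days did not pass within the GC bound (-0.09, adjusted p = 0.337), which leaves out BALB/cJ at day 2 and DBA/2J at day 90. In AKR/J and DBA/2J the Elovl2 effects had opposite signs, but the DBA/2J value turned to 0.14 with the GC offset.

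The first pattern weighed is the count of 9144 genes in DBA/2J at day 90, where 7 of 8 RC libraries lie beyond the GC bound. Fold change followed GC content across genes (r = 0.771), as GC bias requires, but 5292 genes passed with the GC offset, so GC content as fitted is not the whole cause. After that correction a diet score over 4309 genes still followed the GC slope among the 8 RC libraries (r = 0.977, rho = 0.976, exact p = 4.96e-05). The genes of the score and their signs were taken from the DBA/2J contrast that holds these same libraries. The permutation does not allow for that choice. The HFHS libraries with the lowest slopes, 2HF136 (-1.66) and 2HF135 (-0.508), scored -0.551 and -0.238, and the other HFHS libraries 0.00273 to 0.214. With the slope as a covariate 3443 genes passed, 1634 of them with the same sign among the 9144. A linear term shared by all strains need not remove every library defect, so this count does not show whether such defects are the whole cause. The fold changes of DBA/2J and AKR/J correlated with r = 0.358 (rho = 0.443) over 10846 genes, and other splits of the 16 DBA/2J mice reached 0.678 (exact p = 0.233 over 12870 splits). The diets differ in library quality (mean GC slope apart by 0.961), so a diet response shared with AKR/J and library quality cannot be told apart. A bound written beforehand would have excluded the shared response at that p. It was wrong, because a p that misses a threshold does not show that a relation is absent. Over the splits r followed the difference in mean GC slope (r = 0.571), but the 3000 splits with a higher r in size did not differ more in slope (median 0.252) than the others (0.265), so what sets those splits apart is not known.

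The second pattern is the 9 libraries whose strain genes match another strain. GC bias is argued against, since all 9 were again closest to another strain with the GC curves removed. Mixed RNA stays open in all 9. A first rule, genes of 2 or more strains at 10 to 90 percent of their usual level, was met by 1RC133 and by 0 of the other 8, but could not register a small share. A second rule was genes of another strain above their highest level in the matching libraries of the closest strain. It was met by 6 of the other 8 and for 0 strains in 1RC133 (27.8 percent for 129S2/SvPas and 21.6 for C57Bl/6J, with medians of 3.18 and 8.78 in BALB/cJ). There 0 strains was at first to exclude mixing, a bound eased once seen, since these values lie at the top of the BALB/cJ range. Among single genes in 1RC133, Col6a6 (13.8 CPM) and Rnf150 (14.2) were above their highest in BALB/cJ (5.78 and 11.7), while Gdpd3 (10.6) was under its highest (12.7). The 51 matching C57Bl/6J libraries lay within the GC bound, and the libraries set against them beyond it. So the second rule does not separate mixing from library quality there. In these libraries mixed RNA and another cause cannot be told apart. A wrong label may explain the other 8, where the genes of the resembled strain were at 79.6 percent or more of their usual level. Those of the labelled strain were at 3.09 to 17.3 percent. The bound tried first, at least 50 and at most 10 percent, was met by 6 of the 9, and 2 bounds tried afterwards by 5 and by 9. The limit of 10 percent cannot decide for libraries closest to 129S2/SvPas. Matching 129S2/SvPas libraries themselves had C57Bl/6J genes at a median of 10.4 percent and at most 16.8, against 14 in 1HF155 and 17.3 in 1HF156. With these bounds a wrong label and another cause cannot be told apart. An exchange between C57Bl/6J at day 90 and 129S2/SvPas at day 2 also stays open. On a time score 5 of the 8 were closer to the time point of the other group. Those labelled C57Bl/6J, 1HF155, 1HF156 and 1RC134, all were (-1.28, -1.5 and -1.29, with 129S2/SvPas at -1.08 at day 2 and 0.0184 at day 90). Those labelled 129S2/SvPas were mixed, with C57Bl/6J at -0.963 at day 2 and -0.16 at day 90. Here 6HF6 (-0.209) and 6RC2 (-0.113) were closer to day 90, and 6HF5 (-0.673), 6RC5 (-0.777) and 6RC6 (-0.667) to day 2. The score placed 20 of 21 other libraries beyond the GC bound, and all but 2 of those tested within it, at their labelled day.

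The third pattern is the negative correlation of Elovl2 with Ins2 across mice. If it came from insulin RNA taking a varying share of the reads, scaling to the total without the reads of Ins1 and Ins2 would have removed it, but r was -0.612 with that scaling (-0.727 scaled to all reads), which argues against the insulin share as the whole cause. Within the GC bound these were -0.28 and -0.52, so a part played by the share stays open. With the GC curves removed it was 0.0271, so the GC content of the 2 genes is a candidate explanation. In A/J r was -0.695 within the GC bound and -0.11 with the curves removed. The GC-corrected value differed between strains, from -0.612 in C57Bl/6J to 0.543 in 129S2/SvPas, a difference that was not tested. These 2 labels hold the 9 libraries that resemble another strain. Within the GC bound, which leaves those out, the uncorrected r was -0.268 in C57Bl/6J and -0.188 in 129S2/SvPas. No biological explanation of the relation was tested.

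Each count was set against 100 splits of the same mice into groups of the same sizes, counted by limma and including the real split. Chance can be excluded for day 10 (1 split as large, the real one with 140 genes; highest other 1), day 30 (1; 1484 against 0), day 90 (1; 1989 against 277), AKR/J (1; 1952 against 771), DBA/2J (1; 9056 against 8228), the interaction (1; 7055 against 1829), day 90 minus day 2 (1; 7426 against 4407) and the strain effects (1 each; 516 against 1.2e+02 in C57Bl/6J, 673 against 28 in DBA/2J, 478 against 24 in BALB/cJ, 510 against 44 in A/J, 635 against 4 in AKR/J and 481 against 73 in 129S2/SvPas). The counted values held no GC correction, so excluding chance does not tell a diet effect from a difference in library quality. The real groups differed in mean GC slope by 0.961 in DBA/2J at day 90 and by 0.444 for day 90 minus day 2. For the interaction it was 1.17 (largest over its contrasts). Medians over the other splits were 0.275, 0.0953 and 0.537. Few splits were as large for day 2 (2 splits, 6011 against 7190), time (2, 3951 against 4947) and 129S2/SvPas (3, 13 against 58). By a bound of under 5 percent of the splits chance would be excluded there. It is kept open, since another split gave more genes than the real one. The groups of that split differed more in mean GC slope (0.376 against 0.289 at day 2, 0.297 against 0.0695 for time and 0.0816 against 0.00927 in 129S2/SvPas). Chance cannot be excluded in BALB/cJ (5; 1.5e+02 against 573) and A/J (7; 246 highest, 5 real). In C57Bl/6J limma called 0 genes (edgeR 36), so all 100 splits were as large by construction and say nothing about chance, while the highest gave 8386. Splits that call far more genes than the real one, as in C57Bl/6J, BALB/cJ and A/J, or nearly as many, as in DBA/2J, point to a structure of the samples. The groups of the highest other split differed in mean GC slope by 0.889 in C57Bl/6J and 0.867 in DBA/2J, but by 0.00259 in BALB/cJ and 0.0912 in A/J, where 0 day 90 libraries lie beyond the GC bound, so the structure in these 2 strains is not known.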

How the results depend on the processing

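The GC, strain and slope alternatives and the omission of each day 90 library were chosen after the data were seen; the others were planned. Counts are of genes past the threshold, and each p is adjusted. The cause of a change was not tested unless it follows from the setting.

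With the GC curves as an offset the counts were 3290 at day 2, 332 at day 10, 5292 in DBA/2J, 1060 in BALB/cJ, 6 in A/J, 3419 in AKR/J and 208 in 129S2/SvPas at day 90, and 4134 for day 90 minus day 2. Without the libraries beyond the GC bound they were 3284, 1078, 6767 and 1665 at days 2, 10, 30 and 90, 73 in C57Bl/6J, 2794 in BALB/cJ, 32 in A/J, 5028 in AKR/J, 1281 in 129S2/SvPas, 1854 for day 90 minus day 2 and 5855 for time. That setting gives no DBA/2J value at day 90, since 1 RC library is left, and none for BALB/cJ at day 2, where 0 HFHS libraries are left, so its means at these days and for time are over 5 strains.

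Without the 9 libraries that resemble another strain the counts were 300, 3496 and 5001 at days 10, 30 and 90, 19 in C57Bl/6J, 794 in BALB/cJ, 9 in A/J, 212 in 129S2/SvPas and 6165 for time. With the offset as well they were 697 at day 10, 6030 in DBA/2J, 1483 in BALB/cJ, 13 in A/J, 4122 in AKR/J, 341 in 129S2/SvPas and 5939 for time. With the GC slope as a covariate and without the 9 they were 3553 at day 2, 965 at day 10, 3443 in DBA/2J, 1798 in BALB/cJ, 21 in A/J, 4616 in AKR/J, 486 in 129S2/SvPas, 2386 for day 90 minus day 2 and 6340 for time.

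Voom with quality weights gave 3378, 7941 and 8967 at days 10, 30 and 90, 183 in C57Bl/6J, 1705 in BALB/cJ, 36 in A/J, 5960 in AKR/J, 1041 in 129S2/SvPas, 12702 for the interaction and 10175 for time. The authors' table gave 0 in C57Bl/6J by limma (490 at an unadjusted p under 0.05; 31 by DESeq2), 19 in 129S2/SvPas, and 700, 453, 487 and 448 for the strain effects of DBA/2J, BALB/cJ, A/J and 129S2/SvPas. The samples of 1 comparison alone gave 1875 at day 2, 7633 at day 30, 0 by edgeR in C57Bl/6J (370 at an unadjusted p under 0.05), 4900 in AKR/J and 14 in 129S2/SvPas. The acinar covariate gave 4277 at day 30, and the DESeq2 Wald test 18 in A/J and 219 in 129S2/SvPas. Without mouse 6RC89 there were 7 in A/J and 69 in 129S2/SvPas, and without 129S2/SvPas mice numbered 75 or higher 9 in A/J.

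With the mouse number as a block the counts were 43 in BALB/cJ (415 in those samples alone without it), 0 by edgeR in A/J (1123 at an unadjusted p under 0.05; 18 by DESeq2), 4891 in AKR/J and 10 in 129S2/SvPas. The labels give no pairing. As a hint from the data, 3 of 7 mice in BALB/cJ, 1 of 8 in A/J, 1 of 8 in AKR/J and 4 of 7 in 129S2/SvPas were closest to their own number. In BALB/cJ the mean r was 0.379 within pairs of a number (0.0572 to 0.692) and -0.0534 between other mice, so pairing there stays open; within pairs it was 0.059 in A/J, 0.0737 in AKR/J and 0.0522 in 129S2/SvPas. Of the list calls, 3 held with an estimated correlation.

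Leaving out 1 library moved the count at day 10 from 95 (4RC13) to 204 (4RC14). At day 90 it moved in 129S2/SvPas from 41 (6RC42) to 1.6e+02 (6HF47; 59 higher and 98 lower), in A/J from 0 (4HF42; edgeR, 568 at an unadjusted p under 0.05) to 13 (4HF46), in BALB/cJ from 85 (3HF46) to 845 (3RC46) and in C57Bl/6J from 5 (1RC133) to 184 (1RC134).

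Elovl2 at day 2 was 0.11 within the GC bound (p = 0.0659) and 0.08 without the 9 with the offset (p = 0.0545) or with the slope (p = 0.125). Its fall at day 30 passed at -0.12 by voom, in the day 30 samples alone (p = 0.00119), within the bound (p = 0.00204) and without the 9 (p = 0.0239), at -0.11 on the authors' table (p = 0.0302) and at -0.16 with the acinar covariate. In DBA/2J at day 90 it was -0.24 with size factors (p = 0.069), by DESeq2 (p = 0.0669) or in those samples alone (p = 0.134), and -0.11 on the authors' table (p = 0.284). It turned to 0.14 with the offset (p = 0.145), the offset without the 9 (p = 0.102) and the slope (p = 0.225). Day 90 minus day 2 was -0.06 with the offset (p = 0.391), -0.09 within the bound (p = 0.337), -0.03 with the offset without the 9 (p = 0.631) and -0.04 with the slope (p = 0.669). The C57Bl/6J strain effect passed on the authors' table (0.11, p = 0.0145). Time was 0.02 within the bound (p = 0.744), 0.06 with the offset without the 9 (p = 0.163) and 0.07 with the slope (p = 0.0897).

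Correlations of Elovl2 within the GC bound were -0.122 with Ins1, 0.0758 with Gcg, 0.194 with Pdx1, -0.0322 with Mafa, 0.137 with Elovl4, -0.0404 with Fads1 and 0.078 with Fads2. With the GC curves removed they were 0.0385 with Ins1, 0.0271 with Ins2, -0.0716 with Slc2a2, 0.176 with Pdx1, 0.0369 with Mafa, -0.073 with Elovl5, 0.0408 with Fads1, 0.328 with Fads2 and 0.0995 with Scd2.

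Among named genes, H2-Ea-ps in C57Bl/6J was 0 within the bound, without the 9 and with the offset without the 9, and Dnahc17 was 0.35 by voom, 0.33 within the bound, 0.34 without the 9, 0.36 with the offset as well and 0.37 with the slope. By construction, 1RC133 is left out of these but the first. Voom turned Hmha1, Cd52 and Arhgdib in BALB/cJ to -0.46, -0.40 and -0.27, and the slope turned Ins1 and Ins2 at day 30 to -0.20 (p = 0.00582) and -0.15 (p = 0.0195). Of 260 single values, which leave out Elovl2 values such as the DBA/2J one given above, the call or its absence held for 260 with size factors, 256 without a filter, 257 with the acinar covariate, 260 without 6RC89, 252 without the 9, 234 with the slope and 217 by voom. It held for 211 of 246 within the bound, 257 of 259 with the offset, 247 of 259 with the offset without the 9, 247 of 248 by DESeq2, 222 of 256 on the authors' table, all but 26 of 181 in the samples of 1 comparison and 20 of 41 with the block. DESeq2 gives no interaction value, and the samples of 1 comparison no strain, time or day 90 minus day 2 value.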

Other observations

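The tests in this part that were chosen after the result was seen are the gene overlaps between strains and the readings of single libraries; the gene lists were planned.

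On HFHS at day 2, 8 of 15 clock genes rose and 4 fell. Npas2 fell by 0.96 (SE 0.094) and Nfil3 by 0.65 (SE 0.0696), while Per3 rose by 0.72 (SE 0.0916), Hlf by 0.59 (SE 0.0738) and Tef by 0.56 (SE 0.0646), and at day 30 Arntl fell by 0.38 (SE 0.0658). In BALB/cJ at day 90 Nr1d1 rose by 1.38 (SE 0.312), Dbp by 1.21 (SE 0.289) and Cry1 fell by 0.62 (SE 0.136), while in AKR/J the clock list was called down (0.0404, and 0.43 with an estimated correlation). A difference in feeding time or in the hour of islet isolation between diets may explain this; the list at day 2 had no call as reported (camera adjusted p = 0.0728) or without the 9 libraries (0.198), and was called up with the GC offset (0.000101), within the GC bound (0.00333) and with the slope covariate (0.0127) at a preset correlation, settings in which 3290, 3284 and 3553 genes passed. Sampling islets of both diets at several hours of the day would test it.

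In AKR/J at day 90 Aldh1a3, 16 of 25 ER stress genes and 21 of 32 cell cycle genes rose. With an estimated correlation the ER stress call held (adjusted p = 0.0278) and the cell cycle call was lost (0.44). In all, 1939 of its 2054 genes passed with the same sign with the GC offset, within the GC bound, without the 9 libraries and with the slope covariate. The 8 AKR/J mice of each diet held 0 libraries beyond the GC bound and none of the 9, so leaving those libraries out kept every AKR/J mouse. Across genes the AKR/J fold change hardly followed GC content (r = 0.0487), so the other settings could move little. That agreement is therefore no test of the AKR/J response. A hypothesis is that AKR/J islets met a higher secretory demand, while proliferation stays open; the count was 3419 with the GC offset and 5028 within the GC bound. Measuring insulin, glucose and labelled nuclei in the same mice would test it.

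AKR/J and DBA/2J shared called genes beyond the number expected, with the GC offset and without the 9 libraries. Of 16266 genes tested, 2421 were higher in AKR/J and 2600 in DBA/2J, with 907 shared against 387 expected, and 1701 and 3430 were lower, with 754 shared against 359 expected. Lower in AKR/J and higher in DBA/2J were 58 (272 expected), and the opposite 1.6e+02 (511 expected). A common response may lie behind this, but the permutation p of their fold changes was 0.233. Whether it is one of these 2 strains alone stays open. Over all genes compared, AKR/J correlated with BALB/cJ at r = 0.379 (0.356 with the GC offset) and with DBA/2J at 0.211 (0.32). By rank the order was the other way, with rho = 0.164 for BALB/cJ and 0.346 for DBA/2J. Intestinal genes with very large changes can move r, such as Akp3 (-10.33 in AKR/J, -5.8 in BALB/cJ and 8.02 in 129S2/SvPas). AKR/J with 129S2/SvPas had r = -0.521 but rho = -0.0153. No r was computed without these genes, so r gives little ground for a response shared with BALB/cJ. New DBA/2J chow libraries without GC bias would decide.

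Of 28 fatty acid oxidation genes 17, 8, 12 and 10 rose at days 2, 10, 30 and 90, and Cpt1a passed at each of them (0.56, 0.74, 0.65 and 0.48). The list calls were lost with an estimated correlation (adjusted p = 0.508, 0.0902, 0.0942 and 0.44). This is what fatty acids acting through PPAR receptors could give, and Cpt1a also passed at each time point with the GC offset (0.58, 0.76, 0.65 and 0.48). A receptor antagonist in cultured islets would test it. At day 2 adipocyte genes rose as well, so fat taken with the pancreas is a further candidate there, which was not tested.

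Single libraries held transcripts of other tissues. Apoa4, an intestinal gene, was at 3730 CPM in 6HF17, 3040 in 6HF30, 1970 in 4HF3, 1380 in 6HF1, 1070 in 2HF111, 517 in 1HF147 and 458 in 1RC134, and at most 0.025 in AKR/J HFHS at day 90. Adipoq was at 11.2 CPM in 3HF4, 6.62 in 3HF6, 5.62 in 4HF4, 5.25 in 3HF3, 3.08 in 3HF1 and 2.84 in 4HF6. Pieces of gut or fat taken with the pancreas may be the source, and the fall of Apoa4 from day 2 to day 90 in the diet effect did not pass within the GC bound (-5.30, adjusted p = 0.166). Picking islets again under the microscope before lysis would test it.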
